A study of Mus musculus with 2 samples.

How the data were processed

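Single-cell RNA sequencing of spleen T cells was analysed from 2 libraries, LatY136F and LatY136F CD45-KO, 1 per genotype. Per the labels' protocols, cells from spleens of 8 to 9-week-old mice were sorted for CD3 and CD5 and captured with the BD Rhapsody system, and whole transcriptome libraries were made. The series' design text also names a CD4 antibody among the stains, and whether CD4 was part of the gate is not given in the sources used here. Each group was labelled with sample tags, per the labels' protocols. No map from cells to tags was used here, and the number of mice behind each library is not given in the sources used here, so each library is 1 sample. The deposited files hold counts of molecules per cell and gene, after the correction of UMI errors by the authors' pipeline, with cells in rows and no further normalization. Per the file headers, they were made with the BD whole transcriptome pipeline version 1.9.1, the GRCm38 genome and GENCODE M19. The series' design text names pipeline version 2.0 and Seurat 4.04, and the submitters' processing notes name GRCm39. These statements differ, and the file headers were followed. Gene locations were taken from GENCODE M21, which is also on GRCm38.

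The total counts were 35300371 UMIs in the LatY136F library and 29268453 in the CD45-KO library. Of 22686 genes listed in either file, 18318 were listed in both; a gene absent from a file was given a count of 0. Cells with at least 200 genes and at most 25% of counts from mitochondrial genes were kept, which removed 28 LatY136F and 11 CD45-KO cells. Median mitochondrial shares were 8.59% and 9.41%. Both libraries were clustered together with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.8), without antigen receptor, mitochondrial, ribosomal and sex-linked genes and without Ptprc. Scrublet scores were computed per library with an assumed rate of 6%. Its automatic threshold marked 0 cells in both libraries, so doublet calling did not work, and doublets were kept.

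A cluster was named from fixed marker lists. The rule for applying them was set after seeing the data. It asked for at least 3 markers with a log2 fold of at least 1 over all other cells and a UMI in at least 10% of the cluster's cells, and for at least 1 marker among the top 10 genes by fold. Of 10 clusters, 1 was proliferating-like (14 markers), 1 Tfh-like (8 markers) and 1 interferon-response-like (12 markers). Another carried B, plasma cell and monocyte markers and is called non-T. The 6 others stayed unnamed, with 89.8% of LatY136F and 91.9% of CD45-KO cells. All clusters except the non-T cluster are called T-like, and their cells (13715 and 12718) were summed per library for gene ratios.

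Ratios of CPM were computed from the summed counts, with exact conditional binomial 95% intervals for 2 Poisson counts, and shares have exact Clopper-Pearson intervals. Both cover counting error only, and neither covers differences between mice or captures. A count of 0 was set to a floor of 3 counts. No test was run, because cells of 1 library are not replicates. List medians cover members with at least 20 counts over both libraries and are given with their percentile among 10000 random lists of the same size matched on mean expression, which describes these libraries alone. The resampled ranges of the early gene median are the central 95% of 10000 draws of the members with replacement. Interval coverage was checked on simulated Poisson counts for the gene ratios over T-like cells, with 50 genes at each fold among 3489 genes. The intervals assume that same model, so the check covers the computation alone and not variation between cells, mice or captures. The intervals covered 98.0% of genes at a fold of 2, 96.0% at 0.5, 92.0% at 4 and 100.0% at 0.25, and 95.3% of unchanged genes. For shares of cells with a UMI each cell was thinned to 1000 UMIs.

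The main comparisons with their intervals, the cell filters, gene lists, markers and the rule for naming genes were fixed before the data were examined. Some tests of explanations were chosen later and are named where they are given. Ptprc and Lat are named first. Over T-like cells, the 12 highest and 12 lowest genes with at least 50 CPM in at least 1 library are named, ranked by the interval bound nearest 0. Receptor segments, mitochondrial, ribosomal, haemoglobin, sex-linked and unnamed genes are left out of that ranking. In each list, up to 4 members with the largest absolute ratio and at least 20 CPM in at least 1 library are named, and members that serve as class markers may be added. In each class with at least 100 cells in both libraries, the 5 highest and 5 lowest genes are named. Some genes that this rule or the fixed list for shares of cells names are not reported here. Il10, Ccr9, Ly6c1, Fos, Junb, Klrd1, Gzmm and Ccl4, members of the fixed lists, are named outside this rule and were chosen after their values were seen. Nr4a1 and Cd69 belong to the genes fixed for shares of cells. Alternatives were at least 500 genes per cell, at most 10% mitochondrial counts, Leiden resolutions of 0.4 and 1.5, 15 principal components, clustering after thinning, other scalings (the median ratio and edgeR 4.0.16 TMM factors, 0.985 and 1.01), equal cell weights, an equal class mix (the 3 named T-like classes and the unnamed cells as 1 class) and other cell gates. The removal of the 6% of cells with the highest Scrublet scores and an equal mix of all 9 T-like clusters were added after seeing the data. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.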

Results

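Single-cell transcriptomes were collected from T cells of the spleen of 8 to 9-week-old mice of 2 genotypes, with 1 library per genotype. LatY136F mice carry a point mutation in the adaptor LAT that removes its binding site for phospholipase C gamma, and are known to develop a T helper 2-type lymphoproliferation. The other genotype also lacks CD45, the receptor tyrosine phosphatase encoded by Ptprc, which acts on the Src family kinases Lck and Fyn. Live cells were sorted for CD3 and CD5. The LatY136F library held 13775 cells and 35300371 unique molecular identifiers (UMIs), with a median of 2153 UMIs and 1214 genes per cell. The CD45-KO library held 12845 cells and 29268453 UMIs, with a median of 1991 UMIs and 1135 genes per cell. Filters kept 13747 and 12834 cells. Because each genotype has 1 library, no difference below has a replicate check and no p-value is given. Intervals are exact 95% intervals for counting error alone, and ratios are CD45-KO over LatY136F on the log2 scale of CPM (UMI counts scaled to the same library total), summed over T-like cells unless another class is named.

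The targeted gene was measured first. Ptprc (ENSMUSG00000026395.16; GRCm38 chromosome 1, 138062861 to 138175708, protein coding) reached 1760 CPM in the LatY136F library and 1183 CPM in the CD45-KO library, a log2 ratio of -0.57 (interval -0.59 to -0.55). Ptprc transcripts were thus lower, but present, in the library labelled CD45-KO. The targeted exons are not named in the sources used here, and reads from outside a deleted part say nothing about the protein, so this value does not check the label. Lat (ENSMUSG00000030742.7; chromosome 7, 126363824 to 126369570) was at 425 and 379 CPM, a ratio of -0.17 (-0.20 to -0.13). Ptprcap, which encodes a protein associated with CD45, was also lower, with 974 and 557 CPM and a ratio of -0.81. Ptprc was lower in the CD45-KO library in each of the 10 clusters. In 7 of the 8 T-like clusters besides the Tfh-like one the ratio lay between -0.61 and -0.74, and cluster 6 had -0.48. The Tfh-like cluster had the smallest difference, -0.17 (-0.24 to -0.10), with 2145 and 1904 CPM. Under the other clusterings and filters tried, the ratio in Tfh-like cells ran from -0.14 to -0.39.

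**Figure D1:**
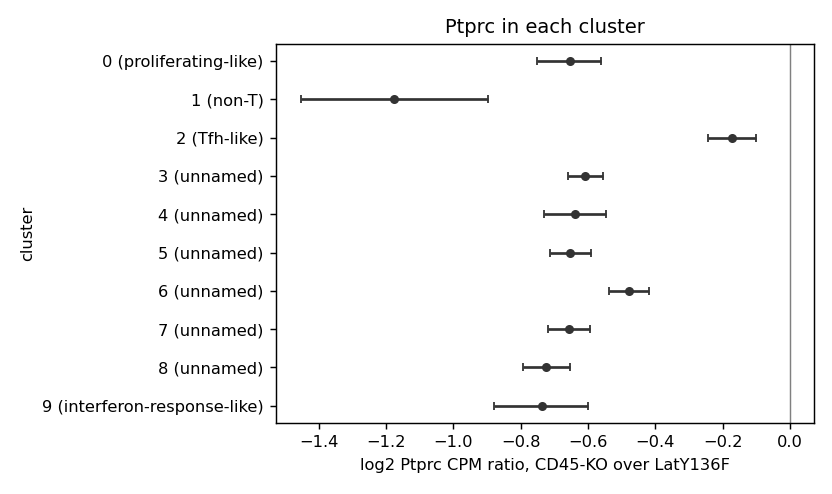
Log2 ratio of Ptprc CPM, CD45-KO over LatY136F (horizontal axis), in each of the 10 cell clusters (vertical axis); points are ratios of summed counts and bars are exact 95% intervals for counting error. Every point lies below 0, from -1.18 in the non-T cluster to -0.17 in the Tfh-like cluster.

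The main comparison asks how the loss of CD45 bears on the activation state of T cells with the LAT mutation. Genes of the cell cycle, the granzyme genes Gzmb and Gzma and several activation genes were lower in the CD45-KO library, and the lists of naive and quiescent genes, early receptor-induced genes and heat shock genes had higher medians. Gzmb, a cytotoxic granule protease, was at 129 CPM in the LatY136F library and 24.0 CPM in the CD45-KO library (log2 ratio -2.42, -2.54 to -2.31), and Gzma at 81.8 and 21.1 CPM (-1.96). Tcf7, the transcription factor of naive and memory T cells, was at 166 and 390 CPM (1.23, 1.18 to 1.28). Ifi208, an interferon-inducible gene of the PYHIN family, had the highest ratio by the fixed rule, from 15.9 to 99.3 CPM (2.64, 2.51 to 2.78).

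Among the other genes with the highest ratios, Selenop, which encodes a selenium transport protein, was at 16.3 and 65.2 CPM (2.0). Ikzf2, encoding the transcription factor Helios, was at 23.1 and 77.9 CPM (1.75). Jun had a ratio of 1.53, Gramd3 1.46, Hs3st3b1 1.40, the integrin gene Itga4 1.25, Arhgap5 1.22, Tbc1d4 1.05, Asap1 1.04 and Fosb 1.00. Itga4 was the most abundant of these, with 292 CPM in the LatY136F library and 693 CPM in the CD45-KO library. On the low side, Kif23, a kinesin of cytokinesis, had a ratio of -1.92, Tmem176b -1.78, the ribonucleotide reductase gene Rrm2 -1.74, Anxa2 -1.62, Pclaf -1.59, Dnase1l3 -1.52, Birc5 -1.48, Ccna2 -1.46, Camk2b -1.43 and the kinase gene Pim2 -1.42. Anxa2 was the most abundant of these, with 459 and 149 CPM. Across the 3693 genes from which these were chosen, the median ratio was -0.01 and 90% of genes lay between -0.50 and 0.39.

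**Figure D2:**
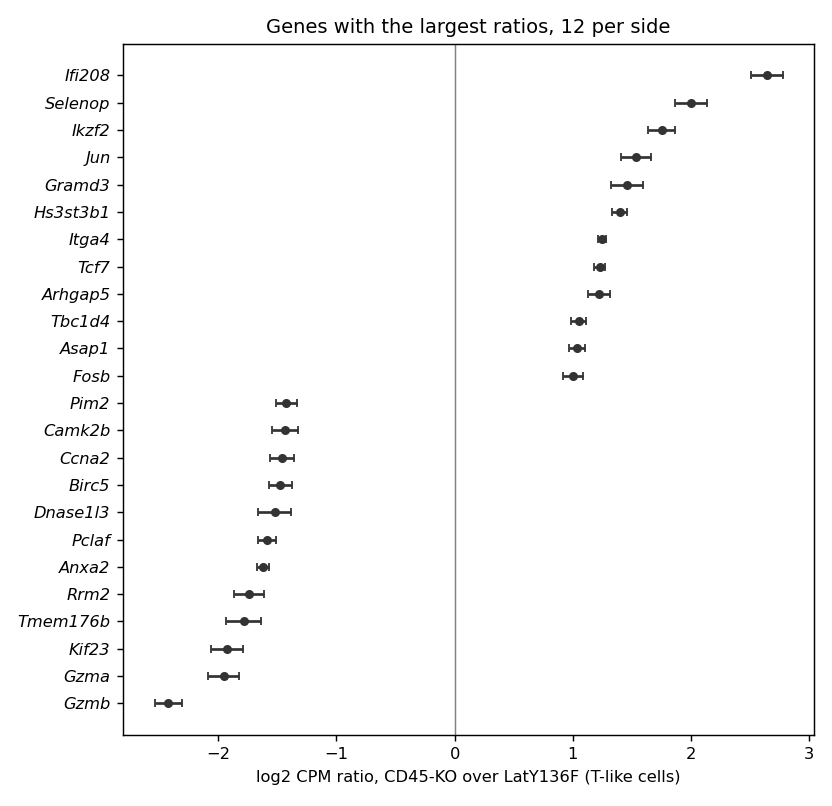
Log2 CPM ratio, CD45-KO over LatY136F, over T-like cells (horizontal axis) for the 12 genes per side with the largest ratios (vertical axis); bars are exact 95% intervals for counting error. Ratios run from -2.42 for Gzmb to 2.64 for Ifi208.

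Proliferation differed in both the share of cycling cells and the transcripts of the cell cycle. Proliferating-like cells made up 5.09% of the LatY136F library (700 of 13747 cells; interval 4.73% to 5.47%) and 1.48% of the CD45-KO library (190 of 12834 cells; 1.28% to 1.70%). All 30 measured cell cycle genes were lower in the CD45-KO library, 24 of them by at least 1.5-fold, with a median ratio of -1.11. This median lay below those of all 10000 random gene lists matched on expression (percentile 0.00). Rrm2 (-1.74), the mitotic kinase gene Aurkb (-1.56), the thymidine kinase gene Tk1 (-1.52) and the survivin gene Birc5 (-1.48) had the lowest ratios, and Mki67 was at 287 and 157 CPM (-0.87). Within proliferating-like cells the median of the list was 0.01 and no member differed by 1.5-fold. With the mix of cell classes held equal the median over all T-like cells was -0.22, and with the mix of all 9 T-like clusters held equal, an alternative chosen after the data were seen, it was -0.18. Among the unnamed T-like cells, which hold 89.8% and 91.9% of the libraries, the list median was -0.66.

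**Figure D3:**
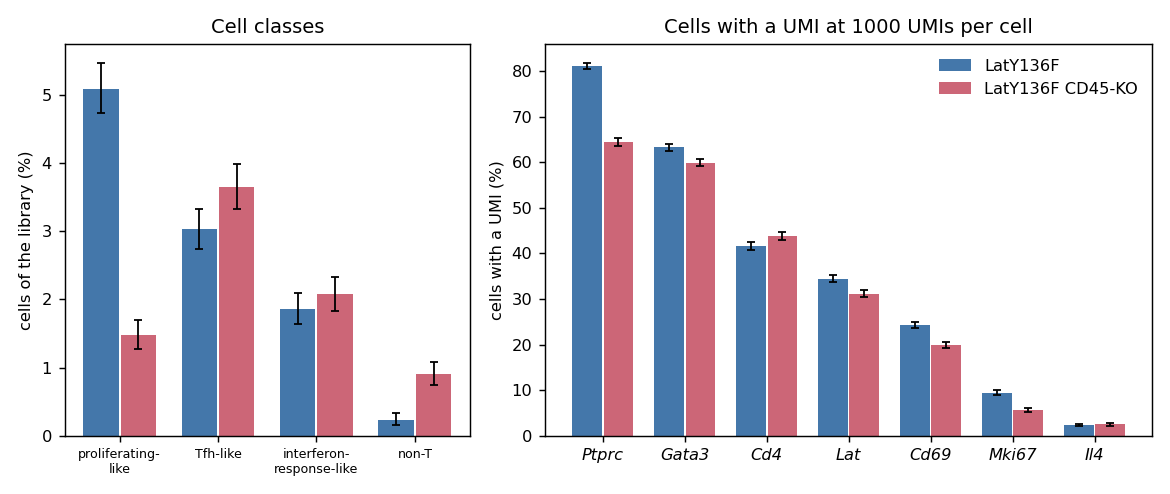
Left, percent of cells of each library (vertical axis) in the named cell classes; right, percent of cells with at least 1 UMI of a gene after thinning every cell to 1000 UMIs. Bars are the LatY136F and CD45-KO libraries and error bars are exact 95% binomial intervals; proliferating-like cells (5.09% and 1.48%) and cells with a Ptprc UMI (81.2% and 64.5%) were both lower in the CD45-KO library.

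As lists, activation genes were lower and genes of naive and quiescent T cells higher in the CD45-KO library, by less with the mix of all T-like clusters held equal (medians -0.19 and 0.26). Of 24 activation and effector genes, 6 were lower by at least 1.5-fold and 1 was higher (median -0.31; percentile 0.00). The lower ones included Anxa2 (-1.62), the interleukin 2 receptor chain gene Il2ra (57.1 and 25.6 CPM; -1.16), Anxa1 (-1.13) and the costimulatory receptor gene Tnfrsf4 (-0.90). The higher one was Itga4. Of 21 naive and quiescent genes, 8 were higher by at least 1.5-fold and 1, Ccr9, was lower (median 0.43; percentile 100). Ly6c1, at a low level, had the highest ratio (1.22 and 13.95 CPM; 3.51). Of the members with at least 20 CPM, Ccr7 (11.02 and 26.2 CPM; 1.25), Tcf7 (1.23), Lef1 (0.87) and Klf3 (0.82) had the highest ratios, and Il7r was at 1291 and 1886 CPM (0.55). In the glycolysis list 15 of 17 genes were lower in the CD45-KO library, 2 of them by 1.5-fold (median -0.26; percentile 0.06). Of the members with at least 20 CPM, Tpi1 (-0.46), Pfkl (-0.45), Ldha (-0.41) and Pkm (-0.38) had the lowest ratios. All 24 nuclear genes of oxidative phosphorylation were lower, none by 1.5-fold (median -0.21, percentile 0.05), led by Uqcr10 (-0.58), Cox5a (-0.54), Cox6c (-0.35) and Cox7a2 (-0.34). With the mix of all T-like clusters held equal the median was -0.17 for glycolysis and -0.07 for oxidative phosphorylation.

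The T helper 2 programme was lower in part. Of 17 measured Th2 genes, 8 were lower by at least 1.5-fold and none was higher by that size (median -0.51; percentile 0.00). Il6 was at 30.9 and 10.9 CPM (-1.50), Plcd1 had -0.77, the interleukin 4 receptor gene Il4ra -0.69 and Nfil3 -0.66. Over all T-like cells the master regulator Gata3 differed little, with 1021 and 982 CPM (-0.06, -0.08 to -0.03), as did Il4, with 36.8 and 31.8 CPM (-0.21). Inside each T-like cluster the Gata3 ratio was below 0, from -0.31 (-0.38 to -0.23) in cluster 3 to -0.03 (-0.10 to 0.03) in cluster 6. Il1rl1, the receptor of interleukin 33, was higher, with a ratio of 0.33. At low levels, Il13 was at 3.76 and 0.88 CPM (-2.10) and Il10 at 2.76 and 0.28 CPM (-3.30).

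Early genes induced by the T cell receptor were higher as a group over all T-like cells of the CD45-KO library, and so were chaperones of the heat shock response. Of 25 early genes, 7 were higher by at least 1.5-fold and 1 was lower (median 0.41; percentile 100). Jun was at 20.6 and 59.8 CPM (1.53), Fosb at 48.6 and 97.4 CPM (1.00), and Myc at 34.6 and 68.1 CPM (0.97). Fos (0.48) and Junb (0.14) stayed below 1.5-fold. With the mix of all 9 T-like clusters held equal, the median of the early genes was 0.11, with a resampled range of -0.14 to 0.32. Within single clusters, the range lay above 0 only in the Tfh-like one (0.38, range 0.21 to 0.70). In the other T-like clusters the medians ran from -0.06 to 0.22, and every range included 0. Irf4, whose level follows receptor signal strength, was lower, with 69.0 and 39.2 CPM (-0.81). Nr4a1 was at 29.8 and 32.5 CPM (0.13, -0.003 to 0.26), and Cd69 at 289 and 256 CPM (-0.17). In the heat shock and dissociation stress list, 7 of 17 genes were higher by at least 1.5-fold and none lower (median 0.45, percentile 100). Unlike that of the early genes, the median of this list stayed at 0.45 with the mix of all T-like clusters held equal. Hspa1b was at 4.53 and 44.1 CPM (3.29), Hsph1 had 0.84, Dnaja1 0.69 and Dnajb1 0.65. Genes of proximal receptor signalling stayed close to 0, with a median of 0.07 (percentile 92.97) and 1 of 30 genes past 1.5-fold, Rasgrp1 at -0.67. Vav1 had 0.37 and Csk -0.36.

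**Figure D4:**
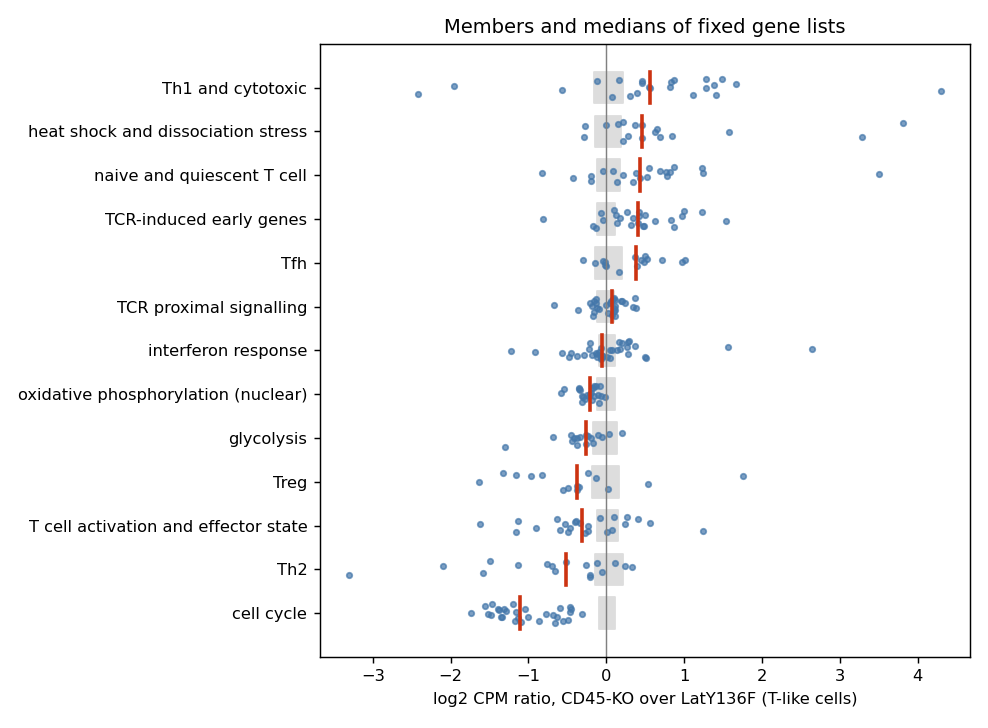
Log2 CPM ratio, CD45-KO over LatY136F, over T-like cells (horizontal axis) for the members of 13 gene lists (vertical axis); blue points are genes, red bars list medians and grey boxes the central 95% of medians of 10000 random lists matched on expression. The cell cycle median is lowest (-1.11) and the Th1 and cytotoxic median highest (0.56).

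Gene groups of other T cell states were mixed. In the Th1 and cytotoxic list 11 of 23 genes were higher by at least 1.5-fold and 2 were lower (median 0.56; percentile 100), and the lower ones were the most abundant granzymes, Gzmb and Gzma. Of the higher ones, Ccl5 (11.7 and 25.3 CPM; 1.12) and Klrg1 (65.8 and 117 CPM; 0.84) were the ones that reached 20 CPM. The marker lists of NK cells (median 0.70; percentile 99.4) and gamma delta T cells (0.52; 99.7) were higher as well, and several of the higher members, such as Klrd1 (0.71 and 1.89 CPM), Gzmm (0.83 and 2.31 CPM) and Ccl4 (0.057 and 1.12 CPM), are NK cell genes at low levels, so the cells that carry this difference are open. The Th1 and cytotoxic median was 0.86 in cells with at most 10% mitochondrial counts, 0.43 with the class mix held equal and 0.35 with all T-like clusters held equal. The gamma delta median was 0.84 and 0.27 under the first and the last of these settings. Trdc, the only gamma delta member with at least 20 CPM, went the other way, with 59.8 and 20.1 CPM (-1.57). Of the NK cell members at that level, Gzma was lower (-1.96) and Eomes higher (0.55). Of 16 Tfh genes 3 were higher by 1.5-fold and none lower (median 0.38; percentile 100); Btla had 0.45, Tox 0.39, Cd200 0.36 and Tox2 -0.31, and the median was 0.18 with the class mix held equal and 0.59 with at most 10% mitochondrial counts. In the unnamed T-like cells the Tfh median had the other sign, -0.17, with 4 of 15 genes lower and 0 higher by 1.5-fold. Of 15 regulatory T cell genes 5 were lower and 1 higher by 1.5-fold (median -0.37; percentile 0.005), with Il1r2 at -1.64, Il2ra at -1.16, Capg at -0.83 and Ikzf2 at 1.75, and the median was -0.59 with the class mix held equal. Foxp3 itself was at 6.32 and 2.52 CPM (-1.32). Interferon response genes had a median of -0.05 (percentile 12.4; 2 of 36 higher and 2 lower by 1.5-fold), with Ifi208 at 2.64, Ifit1bl1 at 0.51 and Ifi27l2a at -0.48. The sign of this median depended on the filters and the class, and it was 0.08 in cells with at most 10% mitochondrial counts. In Tfh-like cells it was 0.34, with 8 of 29 genes higher and 0 lower by 1.5-fold. In the other T-like classes it ran from -0.19 (interferon-response-like) to -0.0007 (proliferating-like).

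Receptor and signalling lists were mixed. Common gamma chain receptors had a median of -0.21 (percentile 0.10), with Il2ra and Il4ra lower and Il7r higher (0.55). Chemokine receptors and homing genes had a median of 0.15 (percentile 98.1), with Ccr7 at 1.25, Itga4 at 1.25, Ccr2 at 0.56 and Itgae at -0.49. The list of inhibitory receptors and exhaustion genes had a median of -0.06 (percentile 25.9), with Rgs1 at -0.67, Ctla4 at -0.56, Btla at 0.45 and Tox at 0.39. The median of this list was -0.24 with cells weighted equally, -0.22 with the class mix and -0.17 with all T-like clusters held equal. It was -0.46 in the unnamed T-like cells, where 5 of 14 genes were lower and 1 higher by 1.5-fold. The Src family kinase and phosphatase list had a median of -0.10 (percentile 6.51), with Lgals3 at -1.08, Ptprcap at -0.81, Ptprc at -0.57 and Lgals1 at -0.39, and its median was 0.03 when non-T cells were included. Apoptosis genes had a median of -0.03 (percentile 22.3), with Cdkn1a at -0.95, Bak1 at -0.82 and Bax at -0.39, and the median ran from -0.13 with cells weighted equally to 0.03 with at most 10% mitochondrial counts. Ribosomal protein genes had a median of 0.21 (71 of 82 higher; percentile 100) and mitochondrially encoded genes 0.22 (10 of 13 higher; percentile 99.6). None of the former and 1 of the latter, mt-Nd3 at -0.65, passed 1.5-fold. With at most 10% mitochondrial counts these medians were 0.13 and 0.12.

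Within the cell classes, part of these differences recurred. In proliferating-like cells (700 and 190 cells) Sostdc1, Nkg7, Ikzf2, Eomes and Tcf7 had the highest ratios, from 1.74 for Tcf7 to 2.31 for Nkg7, and Hdc (-1.85), Ndrg1 (-1.53), Lgals3 (-1.39), Pglyrp1 (-1.26) and Anxa2 (-1.06) the lowest. NK cell markers were higher in this class too (median 3.24, with 4 of 4 measured genes higher by 1.5-fold). So were Th1 and cytotoxic genes (1.01, 10 of 14 higher and 1 lower) and Tfh genes (0.71, 8 of 15 higher and 1 lower). Sostdc1 was also the top gene of the Tfh-like cluster. Cycling NK cells, despite the sort for CD3 and CD5, and cycling Tfh-like cells are therefore not excluded. In Tfh-like cells (416 and 468 cells) Ifi208 (4.46), Iigp1 (3.06), Xcl1 (2.59), Eomes (2.29) and Ms4a4c (1.91) were highest. Il3, a cytokine gene, had 99 UMIs in Tfh-like cells of the LatY136F library and 0 in those of the CD45-KO library, a log2 ratio of -5.07 with the 0 set to the floor of 3 counts and of at most -4.74 by the exact interval. The cells that carried these Il3 UMIs were not counted, and the interval treats the UMIs as independent. Gzma (-4.04), Gzmb (-2.83), Tmem176b (-2.43) and Lgals3 (-2.34) were also lower in Tfh-like cells. Some of these ratios rest on few UMIs in 1 library, such as 5 and 112 for Ifi208 (interval 3.20 to 6.11) and 81 and 5 for Gzma. In interferon-response-like cells (255 and 266 cells) Hspa1a (4.11), Hspa1b (4.03), Ifi208 (2.42), Rgs2 (1.52) and Hsph1 (1.28) were highest, and Tmem176b (-4.37), Gzma (-3.75), Neb (-2.93), Focad (-2.75) and Ecm1 (-2.73) lowest. Counts in the interferon-response-like class were low too. Hspa1a had 2 and 31 UMIs (interval 2.14 to 7.22), Hspa1b 6 and 88, Tmem176b 46 and 2 (-7.45 to -2.43) and Neb 34 and 4. In the unnamed T-like cells Ifi208 (2.52), Ikzf2 (2.06), Selenop (1.96), Jun (1.47) and Gramd3 (1.45) were highest. Gzmb (-2.76), Kif23 (-2.70), Gzma (-2.55), Efna5 (-2.49) and Dnase1l3 (-2.27) were lowest in these unnamed cells. Tfh-like cells made up 3.03% (2.75% to 3.33%) and 3.65% (3.33% to 3.99%) of the libraries. Interferon-response-like cells made up 1.86% (1.64% to 2.09%) and 2.07% (1.83% to 2.33%). The latter shares were 3.43% and 4.60% after thinning, and with at least 500 genes per cell their order turned (2.72% and 2.69%). The 6 unnamed clusters include some that came mostly from 1 library, which may be that library rather than a cell type. Their sizes are not read as shares of cell types. Ifi208, Selenop and Jun were top genes of cluster 8 (3.52% of LatY136F and 38.7% of CD45-KO cells). Gzmb, Efna5 and Dnase1l3 were top genes of cluster 5 (33.4% and 7.19%). Ratios in the unnamed cells thus mix cluster sizes with differences inside clusters. Inside each unnamed cluster Jun was higher (0.63 to 1.32) and Gzmb lower (-2.69 to -1.05). Fos went both ways inside them, from -0.24 in cluster 7 to 0.33 in cluster 4. In the proliferating-like cluster Gzmb was higher in the CD45-KO library (53.4 and 74.7 CPM, ratio 0.48, 0.15 to 0.81).

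Shares of cells with a transcript were compared after thinning each cell to 1000 UMIs, which left out 434 LatY136F and 359 CD45-KO cells with fewer. A Ptprc UMI was found in 81.2% of LatY136F cells (80.5% to 81.9%) and 64.5% of CD45-KO cells (63.7% to 65.4%), against 95.02% and 84.8% without thinning. Mki67, a marker of cycling cells, was found in 9.46% (8.97% to 9.97%) and 5.595% (5.20% to 6.01%), against 16.9% and 9.53% without thinning. The shares for Cd4 were 41.7% and 43.8%, against 66.6% and 66.2% without thinning, and those for Gata3 63.2% and 59.9%, against 84.7% and 80.7%. Cd69 was found in 24.3% and 19.9% of thinned cells and 43.6% and 35.0% of unthinned cells, Lat in 34.5% and 31.2% (59.9% and 52.6%), and Nr4a1 in 2.43% and 2.43% (4.90% and 4.51%). Il4 was found in 2.40% and 2.48% (6.05% and 4.99%), and Foxp3 in 0.436% and 0.144% (0.720% and 0.226%). Cd8a was found in 0.105% and 0.032% (0.138% and 0.078%) and Cd8b1 in 0.188% and 0.248% (0.466% and 0.616%) of cells. A CD4 antibody is named among the stains, and the sources used here do not say whether CD4 was part of the gate, which would set the Cd4 and Cd8 shares. Free RNA sets a background for such shares. The non-T cluster does not measure it cleanly, because its cells also carried T cell transcripts. Without thinning, a Trac UMI was found in 68.8% and 61.2% of them and a Cd3e UMI in 37.5% and 39.7%. Doublets were kept, so free RNA and doublets with T cells cannot be told apart there. In the non-T cluster, 6.90% and 16.7% of the 29 and 114 cells had a Cd4 UMI at the same depth, 20.7% and 16.7% a Gata3 UMI, 3.45% and 0.877% an Il4 UMI and 0% a Foxp3 UMI. A Lat UMI was found in 17.2% and 7.89% of them and a Cd8b1 UMI in 0%, while Cd8a was found in 0% and 0.877%, so with few cells in this cluster the Cd8a, Cd8b1 and Foxp3 shares cannot be told from background. For Mki67 (6.90% and 16.7%), Cd69 (10.3% and 9.65%), Nr4a1 (0% and 2.63%) and Ptprc (69.0% and 39.5%) the cluster is no clean background, because B cells, plasma cells and myeloid cells can express these genes themselves. Background in the Mki67, Cd69 and Nr4a1 shares is therefore open. The Il4 shares of the 2 libraries overlap in their intervals (2.14% to 2.67% and 2.21% to 2.77%), so no difference was detectable at this depth. Mcpt8, a gene of basophils, whose marker list includes Il4, was found in 12.5% and 6.03% of non-T cells without thinning. The Il4 background rests on 1 cell per library (intervals 0.087% to 17.8% and 0.022% to 4.79%). Background in the Il4 shares is therefore open too.

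Markers of cells outside the sort were few. The non-T cluster, with B, plasma cell and monocyte transcripts, held 0.233% of the LatY136F library (32 cells; 0.159% to 0.329%) and 0.904% of the CD45-KO library (116 cells; 0.747% to 1.08%). Its cells were left out of the T cell sums. In those sums the list medians were 0.00 for B cells (Igkc 1.37, Cd74 -0.48, Ighm 0.02), 0.13 for plasma cells (Irf4 -0.81, Ighg1 0.48, Xbp1 -0.32, Edem1 -0.21) and 0.08 for monocytes and macrophages (Ms4a6c 0.77, Cst3 -0.26, Ctss -0.08). They were 0.70 for NK cells (Gzma -1.96, Eomes 0.55), -0.59 for neutrophils, -0.02 for dendritic cells (Bst2 -0.07), -1.70 for erythroid cells (Tfrc -0.47), -0.67 for platelets (Nrgn -1.03), -0.77 for basophils and mast cells (Hdc -1.21, Il4 -0.21) and -0.05 for stromal cells (Col1a1 -1.15, Pecam1 0.06). For other T cell types they were 0.52 for gamma delta T cells (Trdc -1.57), 0.18 for NKT cells (Il2rb -0.40, Cxcr6 0.27) and -0.77 for Th17 cells (Tmem176a -2.04, Tmem176b -1.78, Il1r1 -0.77). The percentiles were 99.4 for NK cells, 99.7 for gamma delta T cells, 0.03 for erythroid cells, 0.15 for Th17 cells and 0.49 for basophils and mast cells, and lay between 10.4 and 81.8 for the others. These lists rest on 2 to 14 measured genes each, and several medians depend on the minimum for members. With members of at least 100 counts the median was -0.19 for erythroid cells, 0.32 for NK cells, 0.04 for neutrophils and -0.54 for stromal cells, and with members of at least 1 count it was -0.19 for erythroid cells, 1.30 for NK cells, 0.48 for plasma cells, 0.15 for stromal cells, 0.30 for platelets and -0.27 for basophils and mast cells. The Th17 median changed sign with members of at least 1 count, from -0.77 to 0.22. With at most 10% mitochondrial counts the erythroid median was -0.83. With the non-T cells included, the medians were 1.62 for B cells, 2.70 for plasma cells and 1.75 for monocytes and macrophages. They were 2.08 for NK cells, 0.855 for dendritic cells and -2.15 for neutrophils. The Th17 median was then -0.30, and the basophil and mast cell median changed sign, from -0.77 to 1.77.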

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

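The tests on depth, handling stress, receptor signalling, the mix of all T-like clusters and the mixture of Ptprc levels were chosen only after the result was seen, or after values close to it; the other tests in this part were not. The planned criteria for the class mix and the chromosome segment used the median or percentile alone, without the resampled ranges used here. By those criteria neither explanation would have stayed open. Signals outside the main measurement stood out in 3 places. The non-T cluster held 0.904% of CD45-KO cells, above the 0.233% of LatY136F cells. Ighe, the heavy chain of immunoglobulin E, was at 18.9 CPM in T-like cells of the CD45-KO library (17.3 to 20.5) and 0.114 CPM in those of the LatY136F library (0.031 to 0.292), where free RNA from the non-T cells was not excluded as the source. In the T cell receptor segments, which were left out of the named genes, Trbv2 made up 23.5% of Trbv UMIs in the CD45-KO library (471 of 2006; 21.6% to 25.4%) and 3.16% in the LatY136F library (82 of 2594; 2.52% to 3.91%). Trbv2 was picked as the Trbv segment with the largest gain in the CD45-KO library. These are shares of UMIs and not of cells, and the intervals treat UMIs of the same cell as independent.

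Cell cycle genes and the share of proliferating-like cells were lower in the CD45-KO library. Depth per cell does not account for it: at 1000 UMIs per cell the LatY136F share of cells with an Mki67 UMI was still 1.69 times that of the CD45-KO library (1.54 to 1.86). Scaling does not account for it either, since the list median was -1.11 by the median ratio and -1.15 by TMM factors. A library or capture batch cannot be told apart from genotype with 1 library per genotype. Fewer cycling T cells without CD45 is therefore a hypothesis that stays open beside the batch.

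Early genes induced by the T cell receptor were higher as a list in the CD45-KO library. A different mix of cell states stays open: the list median was 0.32 (resampled range 0.07 to 0.47) with the named classes held equal and 0.11 (resampled range -0.14 to 0.32) with all 9 T-like clusters held equal, and clusters that come mostly from 1 library can absorb a library difference. Handling or dissociation stress stays open and is a candidate explanation: 10 chaperone genes had a median ratio of 0.56, and all 10 were higher, from 0.21 for Hsp90aa1 to 3.81 for Hspa1a. Stronger receptor signalling stays open as well, since 9 receptor-induced genes had a median of 0.13 and ran from -0.81 for Irf4 to 1.23 for Nr4a3. The genotype itself was not tested apart from these.

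Ptprc transcripts were lower but present in the CD45-KO library. Scaling did not remove the difference (-0.57 by the median ratio and -0.62 by TMM factors). A mixture of cells at the LatY136F level and cells with none would leave 46.7% of T-like cells without a Ptprc UMI at 1000 UMIs per cell, while 34.4% lacked one (33.5% to 35.2%). An even lowering in all cells would leave 32.2%, which is closer but also outside that interval. Other mixtures were not tested. A chromosome segment from another strain stays open: the 83 genes within 20 Mb of Ptprc had a median absolute ratio of 0.19, at percentile 94.0 of random sets, and the resampled range of this median (0.14 to 0.21) reaches past the upper limit of those sets (0.20). A transcript made from the targeted allele may account for the level, which these tables did not test.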

How the results depend on the processing

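The removal of the cells with the highest Scrublet scores and the equal mix of all T-like clusters were chosen only after the result was seen; the other alternatives were planned. No paired analysis was possible because each group has 1 library. The planned removal of doublets marked by Scrublet gave no value, since 0 cells were marked. Every value of Ptprc, of the 5 leading gene lists and of the cell classes kept its sign or its order between libraries, except the interferon-response-like share, which was 2.72% and 2.69% with at least 500 genes per cell. The cause was not tested for any of the values below, except that the mix settings by their construction give both libraries the same share of proliferating-like cells. Depth limits genes near 1 CPM or below, where 1.5-fold can lie within counting error. Of values that do not lead a comparison, 1293 stayed within their counting interval, 429 left it and 12 with an interval clear of 0 changed sign.

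With at most 10% mitochondrial counts the Ptprc ratio was -0.52, the cell cycle median -0.87, the activation median -0.24 and the Th2 median -0.41. In these cells proliferating-like cells were 6.94% and 2.31% of the LatY136F and CD45-KO libraries, Tfh-like cells 2.49% of LatY136F, interferon-response-like cells 2.66% and 2.72%, and non-T cells 1.24% of CD45-KO. Ptprc was -0.59 over all cells, -0.62 by TMM factors, -0.54 with the total without mitochondrial, ribosomal and receptor genes, -0.61 with cells weighted equally and -0.64 with an equal class mix. The early gene median was 0.45 with the reduced total, 0.29 with equal cell weights and 0.32 with an equal class mix, where the cell cycle median was -0.22. With the mix of all T-like clusters held equal, Ptprc was -0.61 and the medians were 0.11 for early genes, -0.18 for the cell cycle, -0.19 for activation, 0.26 for naive genes and -0.36 for Th2. The activation median was -0.35 by TMM factors and -0.27 with the reduced total, the naive median 0.35 with equal cell weights, and the Th2 median -0.38 with all members of at least 1 count.

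With at least 500 genes per cell, Tfh-like cells were 2.50% and 3.31%. Leiden resolution 0.4 gave 5.88% and 1.72% proliferating-like cells and 2.34% Tfh-like cells in LatY136F. Resolution 1.5 gave 5.53% proliferating-like and 3.46% Tfh-like cells in LatY136F, and 2.52% and 2.75% interferon-response-like cells. With 15 principal components, Tfh-like cells were 2.21% of LatY136F and interferon-response-like cells 2.20% and 3.22%. Clustering after thinning gave 5.58% and 1.80% proliferating-like, 2.07% and 3.15% Tfh-like and 3.43% and 4.60% interferon-response-like cells. Without the highest Scrublet scores, LatY136F had 5.49% proliferating-like and 2.09% interferon-response-like cells. This setting and resolution 1.5 also named a Th2 effector-like cluster (3 markers), which the main setting and the other clusterings did not. It held 10.9% of LatY136F and 1.62% of CD45-KO cells without the highest scores, and 11.5% and 3.37% at resolution 1.5. B cells gated by transcripts at 1000 UMIs per cell were 0.113% and 0.273%, a class that differs from non-T.

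Among values with an interval clear of 0, the reversed ones were those of Cd74 (1.07 over all cells, 0.49 in cells gated on T cell transcripts), Cst3 (0.080) and Ctss (0.15) over all cells, Tox2 (0.024 with at most 10% mitochondrial counts) and Cxcr6 (-0.076 with all T-like clusters held equal). The Src list had 0.031 over all cells and 0.0056 when gated, and the basophil list 1.77 and 1.80. With all members of at least 1 count, the Th17 list had 0.22 and the platelet list 0.30. Some medians whose interval includes 0 changed sign too, such as interferon response (0.078 with at most 10% mitochondrial counts, 0.061 over all cells), B cells (1.62 over all cells) and dendritic cells (0.855 over all cells).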

Other observations

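Nothing in this part was planned, and all of its comparisons were chosen only after the result was seen. Plasma cell transcripts differed between the libraries. In the non-T cluster Ighe reached 9662 CPM in the CD45-KO library, where 16 of 116 cells had an Ighe UMI (13.8%; 8.09% to 21.4%). In the LatY136F library 0 of 32 cells had one (exact interval 0% to 10.9%). Ighg1 was at 9592 and 5523 CPM in that cluster of the CD45-KO and LatY136F libraries, from 25 and 6 cells with a UMI. Genes of myeloid cells went different ways there, with Lyz2 at 2960 and 1492 CPM, Ccl6 at 658 and 1283 CPM and Fcer1g at 732 and 772 CPM. Among T-like cells an Igkc UMI was found in 25.9% of the CD45-KO library and 8.41% of the LatY136F library, without thinning. Free RNA was not separated from these shares, and Igkc was at 55710 and 29055 CPM in the 116 and 32 non-T cells of the CD45-KO and LatY136F libraries. Y-linked Ddx3y was at 152 and 162 CPM in the LatY136F and CD45-KO libraries and Xist at 0.142 and 0.376 CPM.

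T cell receptor beta segments had different leading members in the 2 libraries. Trbv13-2 made up 32.2% of Trbv UMIs in the LatY136F library (30.4% to 34.0%) and 13.1% in the CD45-KO library (11.7% to 14.7%). Trbv19 made up 5.44% and 19.9%, and Trbv3 16.9% and 10.2%. The constant segment Trbc1 gave 5.13% of constant region UMIs in the LatY136F library and 9.02% in the CD45-KO library. Counting intervals do not cover differences between mice, whose number is not known here.

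Ifi208 lies 35.6 Mb from Ptprc on chromosome 1, among other PYHIN genes. This block is outside the 20 Mb window, so the chromosome segment was not tested there. Of the 10 other measured members, none was higher by 1.5-fold. Ifi207 (-1.73, at 1.28 and 0.386 CPM), Ifi204 (-1.27, at 111 and 45.9 CPM), Ifi214 (-0.66) and Ifi211 (-0.61) were lower by at least 1.5-fold. The rest ran from -0.06 (Ifi206) to 0.30 (Ifi213), with Mndal at 0.12. These genes were chosen after their values were seen, and closely related copies can share reads. Rgs1 (-0.67) and Rgs2 (0.83), which lie within 20 Mb of Ptprc, went opposite ways.

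The smaller Ptprc difference in Tfh-like cells held under every clustering tried, where it ran from -0.14 to -0.39, while the other T-like cells had -0.56 to -0.61. The difference between these classes was not tested, since there is 1 library per genotype.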
